A study of Homo sapiens with 5 samples.

How the data were processed

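RNA was sequenced from REH cells, an established human precursor B cell acute lymphoblastic leukaemia line that carries the ETV6-RUNX1 (TEL-AML1) fusion, after growth in immunodeficient NSG mice. Per the labels' protocols, leukaemia cells were recovered from the leptomeninges of the brain and from the spleen, purified on a density gradient, and RNA from 5 mice was pooled for each library. The experiment was run on 3 independent occasions, and the spleen pool of the third was left out by the submitters for quality. There were 3 brain libraries and 2 spleen libraries. Libraries were made with a stranded poly(A) kit and sequenced on an Illumina NextSeq instrument, per the labels' protocols. Because pools of different mice were made on separate occasions, the spread between libraries covers occasions and not single animals.

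The submitters' processing notes name bcl2fastq 1.8.4, cutadapt 1.5, kallisto 0.42.4 and DESeq2 without a version, and the builds GRCh38 and GRCm38. The order of steps and the strand setting of the counting are not given in the sources used here. Per the file headers, each library's transcript table holds kallisto estimated counts and TPM, and the transcript names cover 199596 human and 104229 mouse transcripts. The deposited gene table holds estimated counts written as whole numbers for 65217 human gene identifiers. Its library totals differed from the sums of the human transcript estimates by between -18200 and -13800 counts. A further deposited gene table holds log2-scale (rlog) values from the authors, used only as an alternative. Each gene table also holds 1 column that belongs to no sample of the series, which was not used, and the authors' log2 values may have been scaled together with it.

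Human and mouse reads were assigned by pseudoalignment, so reads of near-identical sequences are shared out by a model. Values of HSPA1A and HSPA1B, HSPA6, the metallothioneins, HLA genes with alternative haplotypes, immunoglobulin and T cell receptor segments, ribosomal protein genes with pseudogenes, mitochondrial genes with nuclear copies, the FPGT-TNNI3K readthrough and clustered protocadherins are therefore uncertain. Overlapping and antisense genes are uncertain as well, because the strand setting is unknown.

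Gene identifiers were matched to GENCODE 44 symbols and GRCh38 coordinates. Of the identifiers, 56322 (86.4%) matched and held 99.76% of the counts. Library totals in the gene table were 38387991, 48656936 and 46078731 estimated counts for brain replicates 1 to 3, and 46005806 and 48764202 for spleen replicates 1 and 2. Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with the origin site as the only term, after filterByExpr and TMM scaling. P-values were adjusted by the Benjamini-Hochberg method over the 20419 genes kept, with a threshold of 0.05. The fit had 3 residual degrees of freedom, a prior of 5.9 and a common biological coefficient of variation of 0.148. CPM values were computed here from the estimated counts with TMM-scaled library sizes, standard errors (SE) are on the log2 scale, and fold changes are brain over spleen. SD values cover 3 brain or 2 spleen libraries.

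There were 37 gene lists, of which the 32 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 32 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera takes its p from the 3 residual degrees of freedom, so it has little power with so few libraries. A list that does not pass it is therefore not shown to be unchanged. Fry asks whether the genes of a list move, on balance, in 1 direction, without comparing them with other genes. The mouse share of each library was compared by an exact two-sided permutation test. Exact (Clopper-Pearson) 95% intervals for shares, and intervals of low counts, cover counting error only. For a gene with 0 counts in all libraries of a group, a bound was computed against 3 counts over the group.

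The lists, the tests, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. They were not chosen blind to the study. It was known to concern the metabolism of leukaemia cells in the central nervous system. The sterol and lipid lists were put first, and cholesterol biosynthesis was singled out, for that reason. Genes are named where they were past the threshold with a mean log2 CPM of at least 1, with every brain library on the same side of every spleen library, and were among the 10 largest or 10 smallest log2 fold changes. Up to 3 members of each list past the threshold with the smallest p are also named, or the most abundant member where none passed. HMGCS1, SQLE, INSIG1, SREBF1, SREBF2, SCD, FASN, VEGFA, IL15, CXCR4, CD79A, IL7R and MKI67 were named in any case. Some genes that the rule takes are not reported here.

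Per the labels, a replicate number marks an occasion, so brain and spleen libraries with the same number in their titles were taken as a pair. The spleen columns of the tables carry other numbers than the titles, so this pairing, and each value with the replicate block, is less certain than the groups. The deviations of such libraries from their group means correlated across genes with r = -0.025 for replicate 1 and r = 0.15 for replicate 2; genes are not independent replicates. Log2 CPM values correlated across genes with r = 0.9858 to 0.9894 within brain, 0.9869 within spleen and 0.9753 to 0.9794 between the sites. Replicates differed by more than counting noise, with chi-square per degree of freedom of 16.0 to 42.1 within sites, so no library was a copy of another.

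The test was checked on simulated counts for brain against spleen over 19862 genes. It recovered 79% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold, with 18 false calls. The changed genes were drawn from those with a mean log2 CPM above 1 outside the lists, so recovery of scarcer genes was not checked. In the same simulation a list shifted by 0.5 on the log2 scale had an adjusted p of 1.1e-22 by camera with the preset correlation and 0.0488 with an estimated correlation, and 0 unchanged lists were called by either. Genes were drawn independently there, so the simulation cannot show how often camera calls unchanged lists whose members correlate. In the data the estimated correlation ran from -0.101 for T and NK cells to 0.853 for cytosolic ribosomal proteins. It was 0.453 for cholesterol biosynthesis. Alternatives were the replicate block, DESeq2 1.42.0 size factors, upper-quartile scaling, no filter, a filter of 1 CPM in every library of a group, leaving out each library, transcript estimates summed per gene and rounded, a threshold of 0.1, the DESeq2 Wald test, limma-voom and limma on the log2 values. With the replicate block, the term of replicate 3 fits brain replicate 3 exactly, because the spleen library of that number is missing. That brain library then adds nothing to the fold changes. The block and leaving out brain replicate 3 are therefore nearly the same check of fold changes. The mouse share as a covariate was added after the data were examined. The planned levels of mouse cell type markers were not computed, because the mouse transcripts carried no gene names in the annotation used here.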

Results

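Gene expression was measured in REH leukaemia cells recovered from the brain (leptomeninges) and from the spleen of transplanted mice, to ask how leukaemia cells in the central nervous system differ from those in a peripheral organ. Each of the 3 brain and 2 spleen libraries held pooled RNA of 5 mice. Totals ranged from 38387991 to 48764202 estimated counts on human genes. Along the main axis of variation, which held 46.7% of the variance, the brain libraries lay at -33.6 to -30.2 and the spleen libraries at 47.5 and 48.5. The second axis held 23.3% and did not separate the sites. On it brain replicates 1 to 3 lay at 18.4, 25.4 and -42.2, and spleen replicates 1 and 2 at -23.9 and 22.3.

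In leukaemia cells from brain, 18 of 21 hypoxia response genes and 13 of 20 cholesterol biosynthesis genes were higher and 0 lower, while 10 of 48 nuclear genes of oxidative phosphorylation and 7 of 35 genes of DNA replication were lower and 0 higher. By camera with a preset correlation 20 of 32 gene lists passed, 16 upward and 4 downward. With an estimated correlation 0 passed by camera, and the lowest adjusted p was 0.209. That version rests on the 3 residual degrees of freedom and has little power here. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1228 genes were higher and 714 lower in brain among 20419 tested. The higher genes had a median log2 fold change of 0.90 and the lower genes one of -0.57, and a change of at least 2-fold was found for 564 higher and 107 lower genes. Protein-coding genes made up 1003 of the higher and 654 of the lower genes, and long non-coding RNAs 151 and 29. Leaving out 1 library moved these counts to 515 higher and 146 lower without brain replicate 1, 593 and 249 without brain replicate 2, 844 and 457 without brain replicate 3, 752 and 295 without spleen replicate 1, and 871 and 828 without spleen replicate 2. Higher genes made up 63.2% of the calls, against 51.3% without spleen replicate 2 and 53.1% with the DESeq2 Wald test.

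The largest increases in brain included BHLHE40, a transcriptional repressor induced by hypoxia, CCND2, a D-type cyclin, and VEGFA, the main angiogenic growth factor. BHLHE40 (ENSG00000134107, GRCh38 chromosome 3, 4979437 to 4985323) stood at 38.1 ± 11.9 CPM (SD, n = 3) in brain and 0.767 ± 0.150 (n = 2) in spleen, a log2 fold change of 5.62 (SE 0.317, edgeR adjusted p = 6.08e-05). VEGFA (ENSG00000112715, chromosome 6, 43770184 to 43786487) stood at 27.6 ± 7.60 and 1.38 ± 0.0149 CPM, a log2 fold change of 4.32 (SE 0.258, edgeR adjusted p = 8.34e-05). CCND2 reached 59.9 ± 25.6 CPM against 1.49 ± 0.364, and the transmembrane protein gene ELFN2 61.5 ± 15.7 against 3.10 ± 0.228. The nucleotide sugar receptor gene P2RY14 stood at 13.5 ± 5.17 CPM in brain and 0.143 ± 0.106 in spleen. HSPA6, an inducible heat shock protein gene, had 237, 583 and 422 counts in the brain libraries and 2 and 4 in spleen. The non-coding LINC01416 had 453 counts over brain and 3 over spleen, a ratio of 107 with a counting interval of 36.5 to 523, and all 3 spleen counts came from replicate 1. Its log2 fold change was 10.3 without that library and 5.56 without spleen replicate 2. AK4, a mitochondrial adenylate kinase, and PCP4 had log2 fold changes of 4.22 and 3.60. TIFAB had a log2 fold change of 4.31 that rested on 17 and 0 counts in the spleen libraries, and it was 10.4 without spleen replicate 1 and 3.25 without spleen replicate 2. Every brain library lay above every spleen library for these genes, which the rule for naming them required.

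The largest decreases in brain were smaller. The anion transporter gene SLC26A7 stood at 1.90 ± 0.577 CPM in brain and 8.24 ± 0.829 in spleen, a log2 fold change of -2.12 (SE 0.247, edgeR adjusted p = 0.00167). FCRLA, a B cell protein related to Fc receptors, had a log2 fold change of -1.93. The T cell receptor constant segment TRAC was at 14.9 ± 1.19 CPM in brain against 49.5 ± 11.01 in spleen. APCDD1, UNC13A and MEGF11 had log2 fold changes of -1.59, -1.63 and -1.66, and the readthrough gene FPGT-TNNI3K one of -1.78. The immunoglobulin segment IGLC7 had a log2 fold change of -1.85, and its call was lost without brain replicate 3 or spleen replicate 1 (adjusted p up to 0.0772).

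Of 21 tested members of the hypoxia response list, 18 were higher in brain, 0 were lower and 3 did not pass, with 19 higher when adjusted over the list alone. Their median log2 fold change was 1.26 (camera adjusted p = 3.92e-60; adjusted p = 0.209 with an estimated correlation). BHLHE40, VEGFA and AK4 had the smallest p among them. The glycolysis list, which shares 3 members with other lists, had 6 members higher, 1 lower and 14 not past the threshold of 21, and 7 higher and 1 lower when adjusted over the list alone. Its median was 0.18 (camera adjusted p = 2.19e-09; adjusted p = 0.302 with an estimated correlation), and was 0.274 without brain replicate 1, 0.109 without brain replicate 3 and 0.117 without spleen replicate 2. Of its members, the aldolase gene ALDOC stood at 34.5 ± 7.11 CPM in brain against 4.11 ± 0.138, PFKFB4, a regulator of glycolytic flux, at 28.3 ± 5.93 against 4.16 ± 0.722, and the glucose transporter gene SLC2A3 at 28.1 ± 3.77 against 8.39 ± 0.0349. The most abundant members, GAPDH, ENO1 and PKM, did not pass (log2 fold changes -0.049, -0.10 and -0.066), and the lower member was GPI (-0.52). Summed over the list, levels overlapped, at 10060, 11640 and 11460 CPM in brain and 11590 and 9843 in spleen.

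In the cholesterol biosynthesis list, 13 of 20 tested members were higher, 0 lower and 7 not past the threshold, and 14 were higher and 2 lower when adjusted over the list alone. The median log2 fold change was 0.56 (camera adjusted p = 6.69e-20; adjusted p = 0.23 with an estimated correlation). FDFT1 (squalene synthase, ENSG00000079459, chromosome 8, 11795573 to 11839395) stood at 213 ± 23.6 CPM in brain and 43.4 ± 4.87 in spleen, a log2 fold change of 2.30 (SE 0.136, edgeR adjusted p = 8.23e-05). SQLE, squalene epoxidase, was at 83.5 ± 16.6 against 19.7 ± 0.109 CPM, and HMGCS1, which makes the precursor of mevalonate, at 123 ± 16.3 against 44.4 ± 1.47.

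In the list of cholesterol uptake and SREBP control, 6 of 13 tested members were higher, 0 lower and 7 not past the threshold, with 8 higher when adjusted over the list alone. Its median was 0.38 (camera adjusted p = 3.93e-19; adjusted p = 0.209 with an estimated correlation). STARD4, a sterol carrier (ENSG00000164211, chromosome 5, 111496033 to 111512590), stood at 18.9 ± 0.998 CPM in brain and 1.70 ± 0.0885 in spleen, a log2 fold change of 3.47 (SE 0.153, edgeR adjusted p = 3.84e-05). SREBF2, the transcription factor of sterol genes, was at 262 ± 21.2 against 63.6 ± 3.03, and INSIG1, which retains its precursor in the endoplasmic reticulum, at 170 ± 22.7 against 34.1 ± 8.18. Among LXR targets and sterol efflux genes, 3 of 9 were higher, 1 lower and 5 not past the threshold, with 4 higher and 1 lower when adjusted over the list alone (median 0.34, camera adjusted p = 0.000523; adjusted p = 0.23 with an estimated correlation). The median was 0.163 without brain replicate 3, 0.210 without spleen replicate 1 and 0.211 with the replicate block. The 3 higher members were the efflux transporters ABCG1 (16.5 ± 0.963 against 1.45 ± 0.668 CPM) and ABCA1 (26.3 ± 2.68 against 5.32 ± 3.47 CPM) and the ubiquitin ligase gene MYLIP (23.1 ± 3.18 against 8.65 ± 0.0504 CPM).

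In the list of fatty acid synthesis and desaturation 9 of 23 members were higher, 1 lower and 13 not past the threshold, the first 2 counts being also 9 and 1 when adjusted over the list alone. The median was 0.16 (camera adjusted p = 4.12e-07; adjusted p = 0.302 with an estimated correlation), and 0.254 without spleen replicate 1 or 0.104 without spleen replicate 2. SREBF1, the transcription factor of lipid synthesis, stood at 119 ± 14.3 CPM in brain against 22.2 ± 1.01, the stearoyl-CoA desaturase gene SCD at 159 ± 42.2 against 45.7 ± 8.47, FADS1 at 203 ± 10.6 against 81.0 ± 1.17, and FADS2 at 359 ± 23.6 against 187 ± 5.20. FASN, fatty acid synthase, did not pass the threshold, with a log2 fold change of 0.19 (SE 0.130, edgeR adjusted p = 0.397). In the fatty acid oxidation list 0 of 19 members were higher, 7 lower and 12 not past the threshold, with 8 lower when adjusted over the list alone (median -0.32, camera adjusted p = 6.23e-07; adjusted p = 0.342 with an estimated correlation; fry adjusted p = 0.06). That median was -0.137 without spleen replicate 1 and -0.493 without spleen replicate 2. CPT1A, which commits fatty acids to mitochondrial import (ENSG00000110090, chromosome 11, 68754620 to 68844410), stood at 111 ± 7.19 CPM in brain and 313 ± 12.1 in spleen, a log2 fold change of -1.50 (SE 0.0991, edgeR adjusted p = 0.000138). ETFB, an electron carrier of the pathway, had a log2 fold change of -0.67.

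**Figure D1:**
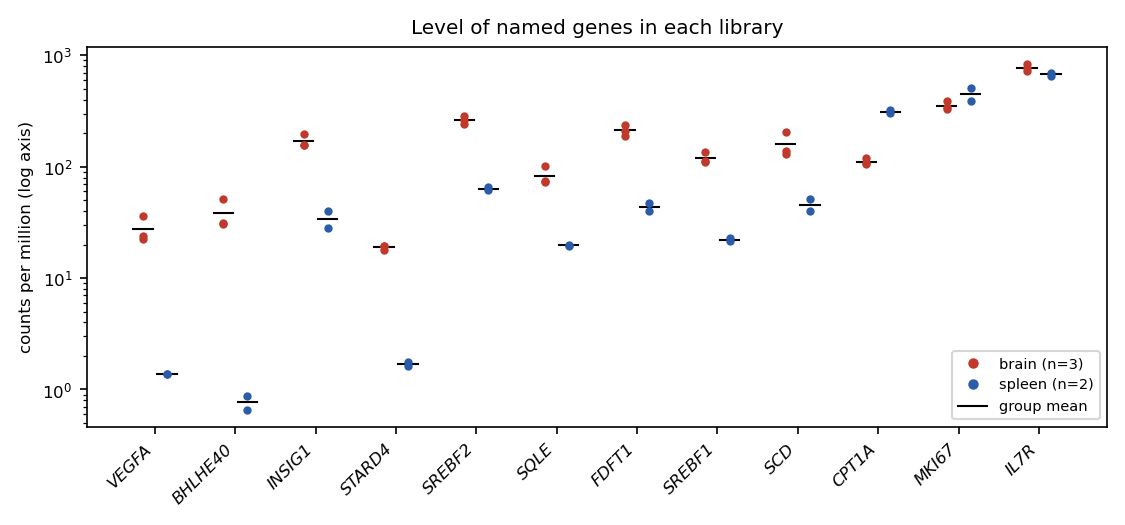
Level of 12 named genes in each library, in CPM on a log axis, with brain (n = 3) in red, spleen (n = 2) in blue and a bar at each group mean. VEGFA, BHLHE40, INSIG1, STARD4, SREBF2, SQLE, FDFT1, SREBF1 and SCD lie higher in every brain library and CPT1A lower, with INSIG1 at 170 against 34.1 and CPT1A at 111 against 313, while MKI67 and IL7R did not pass the test.

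Of 48 nuclear genes of oxidative phosphorylation, 10 were lower in brain, 0 higher and 38 not past the threshold, with 25 lower when adjusted over the list alone. The median log2 fold change was -0.38 (camera adjusted p = 3.96e-11; adjusted p = 0.42 with an estimated correlation; fry adjusted p = 0.164), and -0.177 without spleen replicate 1. ATP5MC1, a subunit of ATP synthase, stood at 58.0 ± 4.97 CPM in brain against 92.9 ± 10.5, and its call was lost without brain replicate 1 (adjusted p = 0.0506). NDUFS7, a complex I subunit, had a log2 fold change of -0.65 and lost its call without brain replicate 1 or spleen replicate 1 (adjusted p up to 0.0819). Of the 13 mitochondrially encoded genes 3 were lower, 0 higher and 10 not past the threshold, also 3 lower when adjusted over the list alone, and the list did not pass (median -0.11, camera adjusted p = 0.055; adjusted p = 0.673 with an estimated correlation). It did pass without spleen replicate 2 (adjusted p = 0.00246), with DESeq2 size factors (0.0499), upper-quartile scaling (0.0427), no filter on low counts (0.0156), summed transcript estimates (0.0411) and the mouse share as a covariate (0.0195, median -0.26). Its median was -0.193 without spleen replicate 2 and 0.0643 without spleen replicate 1 (adjusted p = 0.404). The complex I gene MT-ND2 stood at 1877 ± 26.6 CPM in brain against 3759 ± 213, a log2 fold change of -1.002 (SE 0.0966, edgeR adjusted p = 0.000688). MT-ND1 had a log2 fold change of -0.37 (edgeR adjusted p = 0.0491; 0.0883 with the replicate block), and its call was lost without any 1 of the 5 libraries (adjusted p up to 0.231).

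Of 35 genes of the G1/S transition and DNA replication, 7 were lower, 0 higher and 28 not past the threshold, with 20 lower when adjusted over the list alone (median -0.31, camera adjusted p = 2.29e-08; adjusted p = 0.302 with an estimated correlation). Of 35 genes of G2/M and mitosis, 5 were lower, 0 higher and 30 not past the threshold, with 12 lower when adjusted over the list alone (median -0.29, camera adjusted p = 2.43e-08; adjusted p = 0.232 with an estimated correlation). AURKB, a mitotic kinase, stood at 77.1 ± 13.6 CPM in brain against 115 ± 2.20 and POLA1, a DNA polymerase subunit, at 72.3 ± 4.04 against 96.5 ± 3.65. POLA1 lost its call without any 1 of the 5 (adjusted p up to 0.0973) and AURKB without each except brain replicate 3 (adjusted p up to 0.0926). The proliferation marker MKI67 had a log2 fold change of -0.34 (SE 0.136) and did not pass (edgeR adjusted p = 0.161).

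Stress lists gave mixed results. In the ATF4 and amino acid response list 6 of 23 members were higher and 0 lower, with 7 higher when adjusted over the list alone (median 0.19, camera adjusted p = 8.61e-05; adjusted p = 0.376 with an estimated correlation; fry adjusted p = 0.0825). The median was 0.292 without brain replicate 2, 0.399 without spleen replicate 1 and 0.116 without spleen replicate 2. The amino acid transporter gene SLC7A5 stood at 299 ± 14.8 CPM in brain against 148 ± 15.7, the stress-induced SESN2 at 25.5 ± 1.07 against 12.8 ± 2.32, and the transcription factor gene DDIT3 at 34.97 ± 2.12 against 19.7 ± 2.63. Of 24 immediate early genes 6 were higher and 0 lower, with 7 higher and 2 lower when adjusted over the list alone (median 0.28, camera adjusted p = 0.00603; adjusted p = 0.333 with an estimated correlation), among them JUN, with a log2 fold change of 1.91, and the antiproliferative BTG2, with 1.10. Heat shock genes did not pass as a list, with 3 of 16 higher and 0 lower, 3 higher and 1 lower when adjusted over the list alone (median 0.019, camera adjusted p = 0.08; adjusted p = 0.732 with an estimated correlation). The median was -1.61e-05 under DESeq2 size factors. That list passed without brain replicate 1 (adjusted p = 7.94e-07), brain replicate 2 (0.0234) or spleen replicate 1 (0.0454), with medians of 0.0575, 0.070 and -0.00306. It also passed with the 1 CPM filter (0.0414, median 0.0423) and with no filter on low counts (0.00995, median 0.0117). The median was -0.105 without brain replicate 3 (adjusted p = 0.763), -0.044 without spleen replicate 2 (0.234) and -0.0983 with the replicate block (0.737). Its 3 higher members were the inducible chaperones HSPA1A and HSPA1B, whose reads cannot be told apart with certainty, and DNAJB1, with log2 fold changes of 2.85, 2.20 and 1.14. HSPA6, with a log2 fold change of 7.10, is not on this list.

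Further stress lists did not pass with the filter used here. For the unfolded protein response 3 of 20 members were higher and 0 lower, with 4 higher and 2 lower when adjusted over the list alone (median -0.013, mean 0.09, camera upward with adjusted p = 0.543; 0.759 with an estimated correlation). Of 18 p53 targets 3 were higher and 2 lower, with 6 and 4 when adjusted over the list alone (median 0.21, camera adjusted p = 0.101; 0.337 with an estimated correlation), and this list passed without spleen replicate 2 (adjusted p = 0.0427), with no filter on low counts (0.0198) and by fry (0.0211). Its median was 0.127 without brain replicate 1 and -0.0275 without spleen replicate 1 (adjusted p = 0.152). TP53INP1, a regulator of autophagy and apoptosis, stood at 33.5 ± 4.69 CPM in brain against 6.27 ± 0.613, and BBC3, which encodes the proapoptotic protein PUMA, at 5.34 ± 0.253 against 2.14 ± 0.195. Of 15 genes of NRF2 and iron handling 1 was higher, TFRC with a log2 fold change of 0.63, and 1 lower, NQO1 with -0.98, with 2 and 2 when adjusted over the list alone (median -0.063, camera adjusted p = 0.709; 0.767 with an estimated correlation). NQO1 lost its call without brain replicate 1 or spleen replicate 1 (adjusted p up to 0.076). The metallothionein list had 3 members past the filter, too few for a test as a list. With no filter on low counts it passed downward (median -1.05, camera adjusted p = 0.000379). All 3 were lower in brain, with log2 fold changes of -1.87 for MT1X, -1.42 for MT2A and -0.67 for the zinc exporter gene SLC30A1, which lost its call without any library except brain replicate 2 (adjusted p up to 0.131).

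Of 32 type I interferon response genes 9 were higher and 0 lower, with 11 higher when adjusted over the list alone (median 0.24, camera adjusted p = 9.49e-06; adjusted p = 0.23 with an estimated correlation). The interferon-induced IFI44L stood at 1.95 ± 0.149 CPM in brain against 0.504 ± 0.101, IFIT2 at 8.37 ± 0.147 against 3.73 ± 0.620, and the transcription factor gene IRF7 at 28.6 ± 1.58 against 15.4 ± 2.43. Of 12 MHC class II genes 3 were higher and 0 lower, with 6 higher when adjusted over the list alone (median 0.30, camera adjusted p = 0.00051; adjusted p = 0.342 with an estimated correlation), among them HLA-DQA1 with a log2 fold change of 1.02. MHC class I and antigen processing did not pass, with 2 of 14 higher and 0 lower, also 2 higher when adjusted over the list alone (median 0.12, camera adjusted p = 0.169; 0.732 with an estimated correlation), but did without spleen replicate 1 (median 0.261, adjusted p = 0.00494). Without spleen replicate 2 the median was 0.0239 and camera pointed downward (adjusted p = 0.917). Its higher members were HLA-E, with a log2 fold change of 0.42 (edgeR adjusted p = 0.0375; 0.0601 with the replicate block), and its transactivator gene NLRC5, with 0.53. HLA-E lost its call without any 1 of the libraries (adjusted p up to 0.132) and NLRC5 without each except brain replicate 3 (up to 0.16). Of 19 NF-kB targets 4 were higher and 0 lower, with 5 higher when adjusted over the list alone (median 0.18, camera adjusted p = 0.0489; 0.342 with an estimated correlation). With the replicate block this call was lost (median 0.107, adjusted p = 0.157), as it was without brain replicate 3 (0.102, adjusted p = 0.145) or spleen replicate 1 (0.0926, adjusted p = 0.197). CD40, a receptor of B cell activation, was among them, at 8.56 ± 1.06 CPM in brain against 3.11 ± 0.919.

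Precursor B lineage genes went both ways, with 4 of 26 higher, 4 lower and 18 not past the threshold, and 5 and 5 when adjusted over the list alone (median -0.081, mean 0.024, camera downward with adjusted p = 0.708; 0.754 with an estimated correlation). The tetraspanin gene CD9 stood at 215 ± 11.2 CPM in brain against 115 ± 13.0, the B cell kinase gene BLK at 64.5 ± 3.72 against 110 ± 10.7, and CD79A, a signalling chain of the B cell receptor, at 695 ± 76.4 against 1059 ± 58.8. The call of CD79A was lost without brain replicate 1 (adjusted p = 0.0816). IL7R had a log2 fold change of 0.19 (SE 0.107) and did not pass (edgeR adjusted p = 0.31). Of 77 cytosolic ribosomal protein genes, RPL23A was higher, 0 were lower, and 0 passed when adjusted over the list alone (median 0.17, camera adjusted p = 0.0199; 0.759 with an estimated correlation). This call was lost with the replicate block (adjusted p = 0.289) and without brain replicate 3 (0.474), and turned downward without spleen replicate 2 (0.0146). The median was 0.0856 without brain replicate 3, 0.422 without spleen replicate 1 and -0.0693 without spleen replicate 2. RPL23A (log2 fold change 0.46, edgeR adjusted p = 0.0464) had an adjusted p of 0.0808 with the replicate block and lost its call without any 1 of the libraries (up to 0.15).

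Of 22 adhesion and homing receptors 3 were higher in brain and 0 lower, with 7 higher and 1 lower when adjusted over the list alone (median 0.35, and 0.227 without spleen replicate 2, camera adjusted p = 0.00298; adjusted p = 0.23 with an estimated correlation). PECAM1, an adhesion molecule of leukocytes and endothelium, stood at 13.4 ± 3.66 CPM in brain against 1.43 ± 0.485, the laminin receptor subunit gene ITGA6 at 10.3 ± 1.54 against 1.81 ± 0.438, and ICAM3 at 18.0 ± 0.812 against 9.61 ± 0.970. The chemokine receptor gene CXCR4 had a log2 fold change of 0.37 (SE 0.111) and did not pass (edgeR adjusted p = 0.0701). Of 26 listed genes linked to leukaemia in the central nervous system, 11 are also on other lists. Among the 23 tested, 7 were higher, 3 lower and 13 not past the threshold, with 8 and 3 when adjusted over the list alone. Their median was 0.024 (camera adjusted p = 5.23e-05, and 0.23 with an estimated correlation). The median was 0.134, 0.295 and 0.184 without brain replicates 1, 2 and 3, 0.150 and 0.239 without spleen replicates 1 and 2, 0.186 with the replicate block, 0.00714 with upper-quartile scaling and -0.038 with summed transcript estimates, so its size and sign are uncertain. VEGFA, ITGA6 and TCF4, a transcription factor of B cell development at 366 ± 16.8 against 164 ± 9.49 CPM, had the smallest p among them. The 3 lower members were CD79A and, named after their values were seen, SPP1 and TYRO3, with log2 fold changes of -1.37 and -0.42. The cytokine gene IL15 stood at 2.44 ± 0.181 CPM against 1.25 ± 0.107 (edgeR adjusted p = 0.033), a call lost without any 1 of the 5 libraries (adjusted p up to 0.127).

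**Figure D2:**
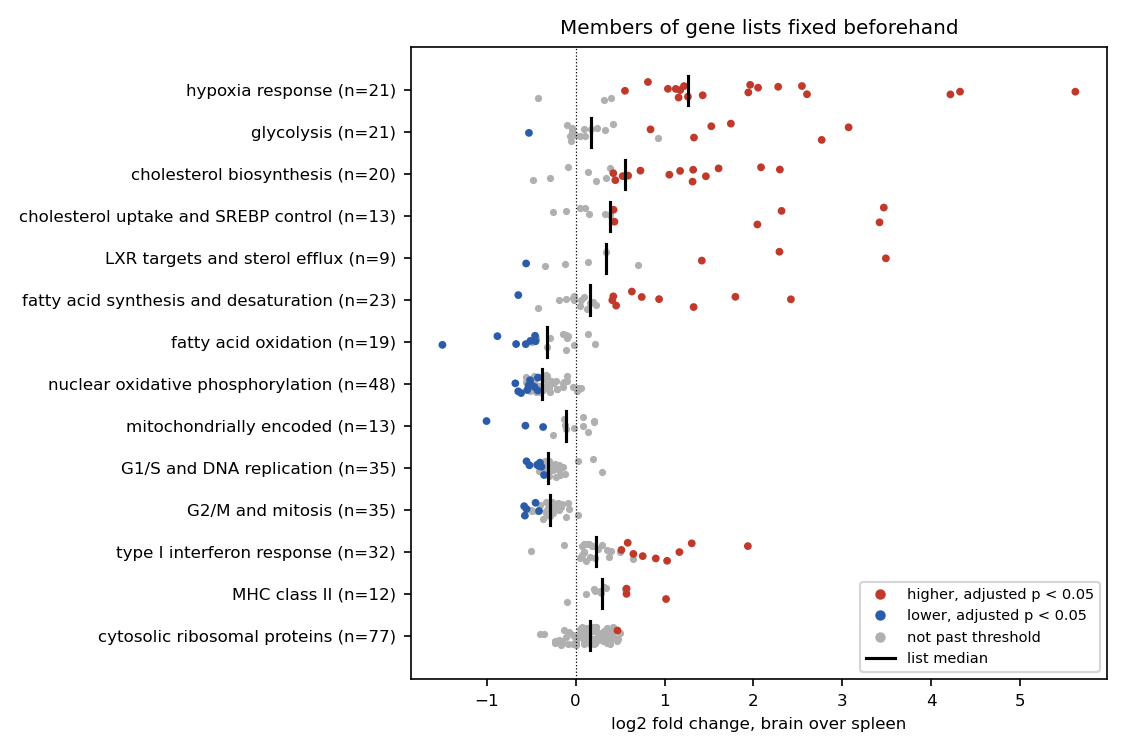
Log2 fold change, brain over spleen, of each tested member of 14 gene lists, with members past an adjusted p of 0.05 in red (higher) or blue (lower), other members in grey and a black bar at the list median. The hypoxia response members lie furthest to the right, with a median of 1.26, and those of nuclear oxidative phosphorylation lie mostly left of 0, with a median of -0.38.

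Lists of markers of other cell types were read in the human counts. Of the 8 tested neuron markers 0 passed in either direction, also when adjusted over the list alone (median -0.10, camera adjusted p = 0.505), and ENO2, the most abundant, was at 30.0 ± 4.53 CPM in brain and 30.2 ± 0.389 in spleen. Of 5 oligodendrocyte markers 0 passed and 2 were higher when adjusted over the list alone (median -0.069, mean 0.305, camera upward with adjusted p = 0.543). Among 7 markers of leptomeningeal fibroblasts 1 was higher, also 1 when adjusted over the list alone (median -0.50, camera adjusted p = 0.942), which was IGFBP2 at 193 ± 31.6 CPM against 51.4 ± 26.0. Endothelial and mural markers had 4 of 10 higher and 0 lower, also 4 when adjusted over the list alone (median 0.46, camera adjusted p = 1.55e-05; 0.272 with an estimated correlation). The median was 0.220 without brain replicate 2 and 0.131 without spleen replicate 1. The higher members included the VEGF receptor gene FLT1 at 15.6 ± 2.25 against 1.88 ± 0.731 CPM and ENG at 124 ± 18.3 against 63.4 ± 0.758. The others were PECAM1 and SLC2A1, which are also on the adhesion and glycolysis lists. Further endothelial and mural markers were near 0 or little changed. CDH5 was at 0.0444 CPM in brain against 0.0114, VWF at 0.242 against 0.142, CLDN5 at 1.52 against 1.35 and RGS5 at 1.70 against 2.03. Microglia and macrophage markers had 3 of 15 higher and 0 lower, with 4 higher when adjusted over the list alone (median 0.30, camera adjusted p = 0.032; 0.614 with an estimated correlation), a call lost with the replicate block (adjusted p = 0.405) and without brain replicate 3 (0.344) or spleen replicate 1 (0.154). The median was -0.214 with the block, 0.522 without brain replicate 2, -0.122 without brain replicate 3 and 1.15 without spleen replicate 2. The mannose receptor gene MRC1 stood at 12.6 ± 1.55 CPM in brain against 3.56 ± 0.207.

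Lists of blood cells other than B cells gave few calls. Of 7 T and NK cell markers 1 was higher and 1 lower, with 2 and 1 when adjusted over the list alone (median 0.015, mean 1.13, camera downward with adjusted p = 0.623), and the median was -0.00389 under DESeq2 size factors. The lower member was TRAC. GZMA, a granzyme gene, had 36, 25 and 17 counts in brain and 0 in both spleen libraries, at least 18.5-fold higher when set against 3 counts over the spleen group. With GZMA at that bound the list median was 0.015 and its mean 0.618. Of 6 markers of megakaryocytes and platelets 0 passed, also when adjusted over the list alone (median -0.72, camera adjusted p = 0.338), and the median was 0.0123 without spleen replicate 2 (adjusted p = 0.917). Lists with under 5 members past the filter were tested as lists only in the settings that gave them 5 or more. There the astrocyte list passed upward with no filter on low counts (median 0.151, camera adjusted p = 0.00192), without spleen replicate 1 (0.503, adjusted p = 0.00604), without spleen replicate 2 (0.87, adjusted p = 0.00174). It also passed with summed transcript estimates (0.761, adjusted p = 0.00012). The neutrophil list passed upward with no filter (median 0.741, adjusted p = 1.72e-07). The erythroid and choroid plexus lists did not pass where tested (adjusted p of 0.364 or more). With the filter, ALDOC, which is also on the glycolysis list, was the 1 higher of 4 astrocyte markers. The receptor gene CSF3R (113 ± 16.6 against 12.0 ± 0.0382 CPM) was the 1 higher of 4 neutrophil and granulocyte precursor markers. HEMGN (0.481 ± 0.140 against 0.0724 ± 0.0379 CPM) was the 1 higher of 4 erythroid markers. When adjusted over each list alone, 2 astrocyte, 3 neutrophil and 1 erythroid markers were higher and 0 lower. The call of HEMGN was lost without brain replicate 1, brain replicate 2 or spleen replicate 1 (adjusted p up to 0.108). The only tested choroid plexus marker, PRLR, had a log2 fold change of -0.52 and did not pass (edgeR adjusted p = 0.471).

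Reads of the mouse host were measured through the mouse transcripts of the index. They took 5.70% of the estimated counts in brain replicate 1 (95% exact interval 5.695 to 5.709), 2.58% in brain replicate 2 (2.576 to 2.585), 2.64% in brain replicate 3 (2.634 to 2.643), 6.33% in spleen replicate 1 (6.325 to 6.339) and 8.87% in spleen replicate 2 (8.864 to 8.879). The mean was 3.64% ± 1.79 (SD, n = 3) in brain and 7.6% ± 1.8 (SD, n = 2) in spleen. The difference of -3.96 percentage points did not pass an exact two-sided permutation test (p = 0.2), for which the 10 arrangements of 5 libraries allow no p below 0.1. Leaving out 1 library moved this difference in the share of reads on mouse transcripts to between -5.23 and -2.69 points. The mouse share of TPM differed by -3.27 points (exact permutation p = 0.3).

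**Figure D3:**
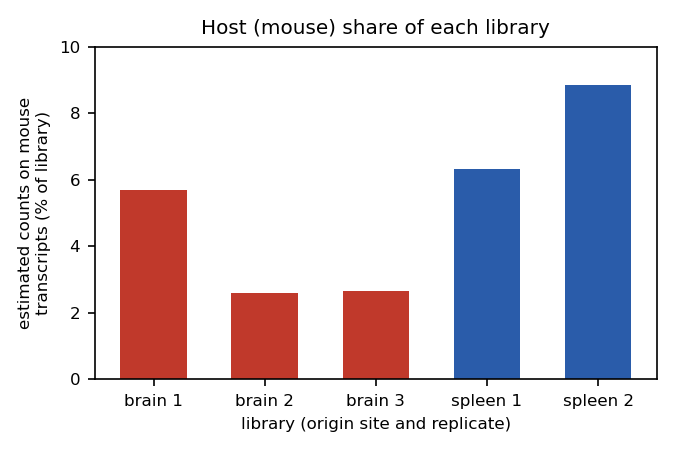
Percent of each library's estimated counts on mouse transcripts, 1 bar per library, for brain in red and spleen in blue, with the axis starting at 0. The brain libraries lie between 2.58% and 5.70% and the spleen libraries at 6.33% and 8.87%.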

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

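The test on stress during cell preparation was chosen after its result was seen, and the fit with the mouse share as a covariate was added after the data were examined; the other tests were set before their results. Reads on mouse transcripts are singled out because they lie outside the comparison of human genes. They took 5.70%, 2.58% and 2.64% of the estimated counts in brain replicates 1 to 3 and 6.33% and 8.87% in spleen replicates 1 and 2.

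The share of host RNA was lower in each brain library than in either spleen library by estimated counts, but not by TPM, where brain replicate 1 had 10.4% and spleen replicate 1 had 7.98%, and it was weighed as a cause of the many genes that differed. With the share as a covariate, 114 genes were higher and 11 lower in place of 1228 and 714. The calls ended mainly through lost precision: the median SE of the genes called without the covariate went from 0.133 to 0.230 with 2 residual degrees of freedom, while their median log2 fold change, in the direction called, was 0.756 against 0.711 before (ratio 1.06, 95% bootstrap interval 1.03 to 1.09). That interval was drawn over genes and not over libraries, and the first fit had chosen these genes. Across the 5 libraries the share also correlated with the origin site (r = -0.814). The fold changes of the called genes thus did not shrink as a set, but the fit cannot decide whether the host share was the whole cause. The medians of the glycolysis, fatty acid synthesis and ribosomal protein lists went from 0.177 to 0.0503, 0.16 to 0.0412 and 0.165 to -0.19. A response to the origin site stays open and was not separable from any other difference between the tissues.

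Higher expression of the hypoxia and sterol lists in brain was set against transcript length and GC content, host RNA counted as human, and stress during preparation. After the trend on length and GC was removed, the median of the 54 members was 0.966 against 1.05 (ratio 0.923, interval 0.918 to 1.24). All intervals for this pattern were drawn over genes and not over libraries. The host brain lists were those of neurons, astrocytes, oligodendrocytes, leptomeningeal fibroblasts and choroid plexus. Their 58 human genes had a median of 0.116 CPM in brain (interval 0.0539 to 0.189), 48 of them under 1 CPM. The hypoxia and sterol members had a median gain of 15.7 CPM (8.93 to 25.7), and 4 of the 58 lay above it. That argues against miscounted RNA of the cells on these lists. The endothelial and mural list and the microglia and macrophage list were not covered. Of their members 4 of 10 and 3 of 15 were higher in brain and 0 lower. Host RNA from such cells was not tested as a cause and stays open. Among the lists covered, that of astrocytes passed upward by camera with no filter on low counts (adjusted p = 0.00192) and with summed transcript estimates (0.00012). Its median was 0.503 and 0.87 without spleen replicates 1 and 2. The 1 called member, ALDOC, is also on the glycolysis list. It held 27.6, 41.8 and 34.1 of the 29.4, 43.5 and 36.0 CPM summed over the tested astrocyte markers in brain replicates 1 to 3. Immediate early and heat shock genes together had a median of 0.139 (interval -0.0469 to 0.342), below that of the pattern but not below 0. That median covers members that went both ways, with 16 of 24 immediate early and 8 of 16 heat shock genes above 0. The highest log2 fold changes in these lists were 1.91 and 2.85, above the median of the pattern. HSPA6, with 7.10, is not on the heat shock list. Handling, as a part or the whole, cannot be told apart from the origin site, because any difference in handling would coincide with it. A response of the cells to that site stays open as an untested hypothesis.

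Lower expression of the cell cycle and oxidative phosphorylation lists in brain was set against length and GC content. With the trend on length and GC removed, the median of the 118 members was -0.303 against -0.32 (ratio 0.947, interval 0.878 to 1.03). That interval was drawn over genes as if they were independent, and not over libraries. The oxidative phosphorylation genes had an estimated correlation of 0.715, so it is likely too narrow. The size of the corrected median still argues against length and GC content as the whole cause. A shift of all genes from the scaling stays open, because TMM, DESeq2 and upper-quartile scaling all assume that most genes do not change and a change in total RNA per cell was not tested. An effect of the origin site stays open as an untested hypothesis, and any difference in handling between the tissues was not tested for these lists.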

How the results depend on the processing

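With the replicate block, which pairs libraries by the number in their titles, an uncertain pairing, 1233 genes were higher and 810 lower. Brain replicate 3, which has no spleen partner, adds nothing to these fold changes. The list medians were thus close to those without that library, such as -0.438 and -0.454 for nuclear oxidative phosphorylation. Losses in these 2 settings are not separate checks. The block changed no calls among the named genes and lists besides those given above (BCL2A1 also lost its call, adjusted p = 0.0504). Without 1 library, between 515 and 871 genes were higher and between 146 and 828 lower, where a lone spleen library is assumed to vary like brain. In those fits 70 of the 102 named genes called kept their call each time. With no filter 1337 genes were lower, and at a threshold of 0.1 there were 1879 higher and 1305 lower. The DESeq2 Wald test, which also changes the scaling and the genes tested (16856), called 1361 lower. With the mouse share as a covariate, added after the data were examined, 114 were higher and 11 lower. That fit had fewer degrees of freedom and a wider error, and it also moved the medians of some lists, given below. Of 110 named genes, 67 lost their call in it. Of 1942 calls, 1827 were kept with DESeq2 size factors, 1908 with upper-quartile scaling, 1776 with limma-voom, 1584 with the replicate block, 1570 with summed transcript estimates, 120 with the mouse share as a covariate, and between 646 and 1189 without 1 library. Of the calls tested again, none turned direction in any setting except 2 with summed transcript estimates. The median over all genes moved by under 0.1 in each scaling.

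Of 32 lists 20 passed by camera and 0 with an estimated correlation (6 at an unadjusted p under 0.05), where cholesterol biosynthesis had an adjusted p of 0.23. LXR targets and genes linked to CNS leukaemia also failed there, with estimated correlations of 0.0162 and 0.0109, close to the preset 0.01. Correlation was thus not the only reason, as that version rests on 3 residual degrees of freedom. Fry gave 16. In the other settings, fry included, the adjusted p of cholesterol biosynthesis stayed between 1.8e-30 and 0.027 and that of the hypoxia response between 1.16e-91 and 0.0193. The ribosomal protein list turned downward without spleen replicate 2 (adjusted p = 0.0146) and with the mouse share as a covariate (0.000205), and lay between 4.07e-20 and 0.474 without 1 library; the cause was not tested. MHC class II (0.326), microglia and macrophage markers (0.209) and immediate early genes (0.132) lost their calls with that covariate, and NF-kB targets lost theirs with upper-quartile scaling (0.0501) and the 1 CPM filter (0.192). With no filter the heat shock (0.00995), p53 (0.0198), mitochondrially encoded (0.0156), metallothionein (0.000379), astrocyte (0.00192) and neutrophil (1.72e-07) lists passed as well. The last 3 have under 5 members with the filter used here. Heat shock also passed with the 1 CPM filter (0.0414), and the mitochondrially encoded list with summed transcript estimates (0.0411) and with the covariate (0.0195). With the covariate the medians of lists that had passed moved by over 1.5 times for glycolysis (0.177 to 0.0503), fatty acid synthesis (0.16 to 0.0412), cholesterol uptake (0.384 to 0.25) and genes linked to CNS leukaemia (0.0244 to 0.346). They also did for nuclear oxidative phosphorylation (-0.379 to -0.594) and fatty acid oxidation (-0.32 to -0.498), and that of ribosomal proteins changed sign (0.165 to -0.19). Among lists that did not pass and are not described so above, a left-out library also changed the sign of the median for the unfolded protein response, precursor B lineage, neurons, oligodendrocytes and T and NK cells. Mouse cell type markers were not run. Genes near 3 counts in a library, such as HSPA6 in spleen, have the least certain fold changes.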

Other observations

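Gene families were looked at after the called genes were seen, so these tests were all chosen afterwards, except that on chromosomes. The p-values of the families were adjusted over the 4 families only. They do not correct for that choice, so they describe the families and are no independent support. Of 7 tested genes of the GIMAP family, GTPases of lymphocytes that lie together on chromosome 7, 6 were higher in brain, with a family median log2 fold change of 1.44 (camera adjusted p = 2.37e-12 over 4 families; adjusted p = 0.048 with an estimated correlation), and medians of 1.42 and 1.43 under DESeq2 and upper-quartile scaling. GIMAP7 had a log2 fold change of 3.26 (SE 0.547, edgeR adjusted p = 0.00955) and GIMAP4 one of 1.44 (SE 0.137, edgeR adjusted p = 0.000678). Clustered protocadherins of the PCDHB and PCDHG families, adhesion molecules best known from neurons, had 7 of 29 higher and 0 lower (median 0.22, camera adjusted p = 0.00888; 0.272 with an estimated correlation). The median was 0.204 and 0.211 under the other scalings. Their near-identical sequences make single values uncertain.

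Of 78 mitochondrial ribosomal protein genes, 21 were lower in brain, 0 higher and the others not past the threshold (median -0.34, camera adjusted p = 3.22e-13; adjusted p = 0.272 with an estimated correlation). MRPL40 had a log2 fold change of -0.82 and MRPS34 one of -0.81. Complex I genes with symbols that start with NDUF, 18 of them in the lists fixed beforehand, had 9 of 37 lower and 0 higher (median -0.44, camera adjusted p = 2.85e-11; adjusted p = 0.272 with an estimated correlation). Under DESeq2 and upper-quartile scaling the medians were -0.359 and -0.347 for the ribosomal and -0.457 and -0.442 for the NDUF genes. Another scaling shifts all genes by nearly the same amount, so it could hardly have changed these signs. Families were not refitted with a library left out. For the nuclear oxidative phosphorylation list the median went from -0.379 to -0.177 without spleen replicate 1.

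Among 20751 mouse transcripts tested, edgeR's test called 2179 higher and 1189 lower in brain libraries. Human genes on the lists of other cell types stood at very different levels. HBB was at 0 CPM in brain and 0.0114 in spleen and S100A8 at 0.053 and 0.0397, while AIF1 was at 74.8 and 72.4, CTSS at 36.2 and 26.8, MPO at 28.5 and 17.0, and CA2 at 22.1 and 20.1.

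A hypothesis that a subclone with another chromosome copy number may have grown in the brain was tested by the median log2 fold change of each chromosome. The largest distance from the median of all tested genes was 0.0648, on chromosome 22, and the widest bound of any bootstrap interval was 0.0966, against the 0.2 set beforehand for such a change. These intervals, too, were drawn over genes and not over libraries. Of 23 chromosomes 0 passed camera (adjusted p of 0.948 or more; 0.885 or more with an estimated correlation), and also 0 had an unadjusted p under 0.05 by either. The data thus argue against a gained or lost chromosome in most cells of a site.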
